A study of Mus musculus with 4 samples.

How the data were processed

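The data are 4 lists of H3K27ac peaks from 4 chromatin immunoprecipitation libraries of heart tissue, per the labels from 2 biological replicates with 2 technical replicates each. Each biological replicate is a pool of 2 heart samples from female B6CASTF1/J mice aged 2 months. The labels give the same donor identifier for both pools, and do not say how many animals it stands for, so differences between the pools may be technical. Which list came from which alignments was taken from the text files deposited beside the libraries. Of the 4 lists, 1 holds replicated peaks derived from the alignments of both biological replicates, 1 holds pseudoreplicated peaks from both, and 1 each holds pseudoreplicated peaks from biological replicate 1 and 2. Technical replicates had been joined before peaks were called, so the lists used here hold no value per library, and replicates were compared through the lists of single replicates.

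Each deposited list gives a position for every peak, a display score, a fold, −log10 values and the distance of the summit from the peak start. The score is the authors' display score. The fold is the authors' ratio for the peak, read as enrichment over a control from the order of columns of this file format. The −log10 p and −log10 q are the authors' values, and the lowest −log10 p was about 2.03 in the replicated list, while q was not limited: 1332 of its 63061 peaks had q above 0.05. Fold, p and q were used only within a list, to rank or filter peaks and to compare the median fold of groups of its peaks. The score was not used. Positions are on mm10 per the labels and the deposited file lists. The aligner, the peak caller and their versions are not given in the sources used here, nor is the number of reads, so depth per library is unknown and the intervals given cover counting of peaks, genes or windows only. Reads of a hybrid of CAST/EiJ and C57BL/6J were placed on mm10 per the labels, and the effect of strain variants was not tested.

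Gene positions, TSSs and exons came from GENCODE release M21 on GRCm38, and sequence from GRCm38, the assembly of mm10. All peak ends lay inside its chromosome lengths. A promoter peak is a peak within 1 kb of any annotated TSS of a gene, a distal peak lies over 2.5 kb from any TSS, and acetylated length is the length covered by peaks from 50 kb before to 50 kb after a gene. Peaks were called shared when they overlapped by at least 1 bp. Chance levels of overlap and location came from 100 circular shifts of the peaks within chromosomes. Regions joined peaks within 12.5 kb of one another and were ranked by covered length.

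Before the data were examined, 31 gene lists, 17 consensus sequences, the tests and most of the alternatives named below were written down. Where 2 annotated genes carried the same symbol, as for Aldoa, Atp5o and Ddit3, the first by position was counted. Some genes, such as Fabp4, Nppa and Tbx18, are shared between lists. Lists with at least 5 protein-coding members were tested, 29 in all. The X-inactivation escape list, with 4 protein-coding members, and the Y-linked list were reported gene by gene. Promoter peaks were compared by Fisher's exact test, two-sided, over 21728 protein-coding genes. Acetylated length was compared by a two-sided permutation test against 10000 random lists with the same number of genes in each of 10 classes of gene length. Both were adjusted by the Benjamini-Hochberg method over 29 lists at a threshold of 0.05. Genes are not replicates, and these tests describe the peak list, not a population of mice. Private peaks were compared with random lists as percentiles only.

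Genes were named by a fixed rule. In each list these were up to 4 members with the most acetylated length among those with a promoter peak, and up to 4 members without one in alphabetical order, those without any peak within 50 kb first. To these were added the gene nearest to each of the 20 longest regions, the 10 protein-coding genes with the widest peak at a TSS, and the X-inactivation escape and Y-linked genes. Further genes in the text, Neat1, Malat1, Klf13, Cidea, Col4a2, Myh6 and the isoforms and families of the closing section, were chosen after their values were seen. Some genes that this rule selects are not reported here.

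A consensus sequence was counted when it stood on either strand of the 500 bp around the summit of a distal peak, and compared with 500 bp windows 5 kb to either side that touched no peak. The odds ratio was a Mantel-Haenszel estimate over 10 classes of GC content. It was set beside 20 shuffles of the same consensus, of which those found in at least 10 windows of each kind gave an odds ratio. A call needed at least 10 such shuffles, which 14 of the 17 consensus sequences had. Both of these limits were set after the data were in hand.

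The tests were run on simulated data first. Of 580 lists with values permuted within classes of gene length, 4.66% had a Fisher p and 4.14% a permutation p under 0.05. Permuting gene by gene removes the sharing of peaks between neighbouring genes, so these rates do not cover lists with neighbours. Of 200 lists given a promoter peak at each gene and 3 times the acetylated length plus a small constant, the tests found 100% and 90.0%. In 20000 random windows of unequal GC content, consensus sequences implanted at an odds ratio of 1.5 gave a median of 1.48, and a median of 1.02 without implant, where 10 of 11 intervals held 1.

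Alternatives were a reciprocal overlap of 50%, peaks in the upper part of the fold ranking (at or above the median), promoter windows of 500 bp and 2.5 kb, the 5' end of the gene alone as TSS, a gene window of 20 kb, leaving out peaks near a TSS, random lists matched on promoter peaks, joining within 5 kb, motif windows of 200 bp and 1 kb, the pooled pseudoreplicated list and each single-replicate list. Chosen after the lists had been seen were a filter at q of 0.05, leaving out genes that share a promoter window, and control windows over 2.5 kb from any TSS. Read-level tracks were not used here. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and samtools 1.23.1.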

Results

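Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in hearts of female mice aged 2 months. The mice were B6CASTF1/J, first-generation hybrids of C57BL/6J and CAST/EiJ. The 4 libraries form 1 group and come from 2 biological replicates, each a pool of 2 heart samples, with 2 technical replicates per pool. There is no second tissue, age, sex or treatment, so the comparisons are between the replicates, between gene groups, between chromosomes and between peaks and neighbouring sequence. The peaks were called by the authors on pooled technical replicates, and no read count is given in the files used here, so sequencing depth is unknown. Positions are those of mouse build mm10.

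The first question is how far the 2 pools of hearts gave the same acetylated regions. The strong regions were shared. Of the 55831 peaks of biological replicate 1, 94.7% overlapped a peak of biological replicate 2 (95% exact binomial interval 94.5% to 94.8%). In the other direction the share was 67.7% of 61333 peaks (67.4% to 68.1%). Peaks moved at random along their chromosomes overlapped in 5.21% and 4.37%. The peaks of replicate 2 were wider, with a median of 930 bp against 664 bp, and covered 81.1 Mb against 54.4 Mb, a ratio of 1.49. Of all sequence covered in either list, 62.8% was covered in both.

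Peaks without a partner were weak ones within their own list. Ranked by the fold that the authors deposited for each peak, the replicate 2 list was divided into 4 equal classes. In the lowest class 76.4% of peaks lacked a partner, in the next 45.4%, then 7.11% and, in the highest, 0.0391%, where 6 of 15333 peaks had none. For replicate 1 the shares were 16.3%, 4.88%, 0.229% and 0%. When peaks had to cover 50% of each other, the overlap was 51.3% of replicate 1 and 46.7% of replicate 2. With 1 list per replicate, there is no test of the difference between the pools.

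**Figure D1:**
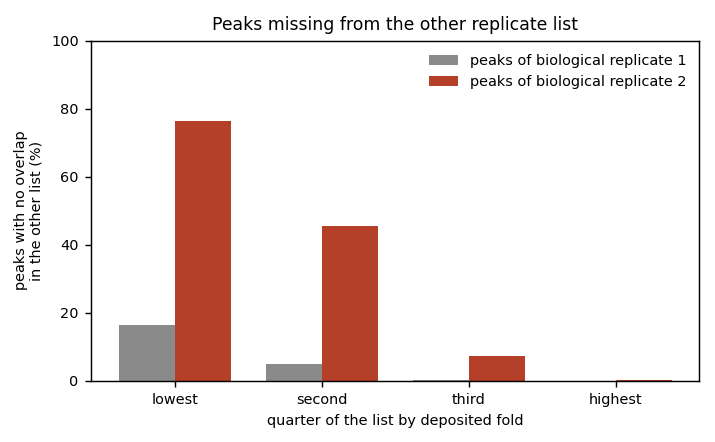
Percent of peaks of each biological replicate that share no base with a peak of the other replicate (y axis), in 4 equal classes of deposited fold (x axis, lowest to highest). Grey bars are replicate 1 and red bars replicate 2. The share falls from 76.4% to 0.0391% in replicate 2 and from 16.3% to 0% in replicate 1.

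The comparisons that follow used the replicated list, 63061 peaks that the authors derived from both replicates, which cover 66.9 Mb or 2.54% of the genome. Of these, 73.0% overlapped a peak in both single-replicate lists and 5.86% in neither. Promoters held a large part of the acetylation. Of these peaks, 32.6% lay within 1 kb of an annotated transcription start site (TSS), against 9.06% of peaks moved at random, a ratio of 3.60. Introns held 39.2% (34.6% at random), exons 6.87% (7.67%) and intergenic sequence 21.3% (48.7%). Peaks at a TSS had a median width of 1051 bp and a median deposited fold of 8.73, against 574 bp and 3.89 elsewhere, and made up 44.1% of the covered length. Distal peaks, over 2.5 kb from any TSS, numbered 37273.

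The next question is which gene groups carried acetylated promoters. The contractile and metabolic genes of heart muscle did so almost without exception. A promoter peak, within 1 kb of a TSS, was present at 20 of 20 sarcomere genes, 20 of 20 genes of calcium handling and electrical activity, 23 of 23 genes of fatty acid oxidation and 15 of 15 genes of glycolysis and glucose uptake. The share among all 21728 protein-coding genes was 57.3%. Among cardiac transcription factors 21 of 22 had one, the exception being Hand1, and among genes of oxidative phosphorylation 19 of 20. The exception, Atp5o, is a matter of annotation: of 2 genes of that symbol the long one that was counted, on chromosome 16 from 91684398 to 91926982, had no promoter peak, and the short one, from 91925214 to 91931687, had one. All 6 groups exceeded the other genes by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted p from 8.06e-05 for fatty acid oxidation to 0.000795 for oxidative phosphorylation).

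Endothelial genes (20 of 20) and fibroblast genes (18 of 18) were acetylated as completely, with adjusted p of 0.00017 and 0.00018. The same held for the circadian clock (18 of 18, 0.00018), heat shock and unfolded protein response genes (12 of 12, 0.0032) and housekeeping genes (15 of 15, 0.000713). Of immediate early genes, which respond within minutes to stimuli, 23 of 24 had a promoter peak (0.000177), Egr3 being the exception. Pericyte and smooth muscle genes had 12 of 15 (0.119), without Cnn1, Lmod1 and Myh11. Lmod1 had a promoter peak in the list of replicate 1 and Myh11 in that of replicate 2. The fetal and stress program of the heart had 10 of 12 (0.104). Nppb, which encodes the natriuretic peptide BNP, had a promoter peak of 1.52 kb. Myh7, the slow myosin heavy chain, had peaks of at most 0.435 kb at its 5' end, with a wider one of 4.15 kb at an internal TSS near its neighbour Myh6. Acta1 and Gdf15 had none, although Gdf15 had a promoter peak in the list of replicate 2.

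Markers of the atria were split. Of 12, 9 had a promoter peak (Fisher's exact test, adjusted p = 0.256), among them Nppa, which encodes the atrial natriuretic peptide, with a peak of 0.938 kb and a deposited fold of 3.70. Bmp10 had no peak within 50 kb, and Myl7, the atrial regulatory light chain, had a promoter peak only in the list of replicate 2. Of 14 conduction system genes 5 had one (0.119). These included Tbx3, Id2 and Irx3, while Isl1 and Vsnl1 had no peak within 50 kb.

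Among genes of blood and accessory cells, the lymphocyte and the epicardial and mesothelial lists had fewer promoter peaks than other genes, and macrophage, erythroid, Schwann cell and adipocyte lists did not differ by the test. Lymphocyte genes had 3 of 15 (Fisher's exact test, adjusted p = 0.0101), namely Cd2, Ikzf1 and Lck, each at an internal TSS and not at the 5' end of the gene, and epicardial and mesothelial genes 3 of 13 (0.0304), namely Cldn15, Tbx18 and Wt1. Macrophage genes had 5 of 16 (0.0567), with Spi1, the myeloid transcription factor PU.1, and Lyve1 among them. The complement gene C1qb had a weak peak of 0.204 kb, and Adgre1, F13a1 and Ptprc had no peak within 50 kb. In the list of replicate 2, however, Ptprc had a promoter peak and Adgre1 had 0.249 kb of peaks in its window. Erythroid genes had 3 of 10 (0.119), with Tal1, Epor and Klf1 acetylated and no peak within 50 kb of the adult beta-globin genes Hbb-bs and Hbb-bt. Schwann cell genes had 3 of 10 (0.119) and adipocyte genes 5 of 14 (0.119). Among the latter Pnpla2, Fabp4, Pparg, Lipe and Cidea were acetylated, and Adipoq, Cfd and Cidec had no promoter peak. Fabp4 is also in the endothelial list, and Lipe had no peak at the 5' end of the gene.

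Genes of tissues other than heart were mostly without promoter acetylation. A promoter peak was found at 1 of 18 hepatocyte genes (Fisher's exact test, adjusted p = 8.06e-05), 1 of 15 neuron genes (0.000194), 1 of 12 keratinocyte genes (0.00121), 1 of 12 photoreceptor genes (0.00121) and 2 of 15 testis germ cell genes (0.00151). These were Trf, Stmn2, Krt10, Sag, and Dazl with Zpbp, of which Krt10 and Sag had no peak at the 5' end of the gene. Skeletal muscle genes had 5 of 20 (0.00846). Tnnt1, Casq1, Mybpc2 and Mylpf were among the 5, and Myod1 and the fast myosins Myh1, Myh2 and Myh4 had no peak within 50 kb. Hox genes, which set position along the body axis, had 6 of 19 (0.0473), with Hoxa3, Hoxa5 and Hoxb3 among them. However, Hoxa3 had no promoter peak in either single-replicate list, and Hoxb3 had no peak at the 5' end of the gene. In all, 12 of 29 lists lay above the other genes and 9 below.

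The call for epicardial and mesothelial genes ended in either single-replicate list (Fisher's exact test, adjusted p = 0.108 and 0.0646), and that for skeletal muscle genes ended with a promoter window of 2.5 kb (0.125). The call for Hox genes ended when genes sharing a promoter window with another gene were left out (0.0589), and macrophage genes passed the threshold, with fewer promoter peaks than other genes, when only the stronger peaks were used (0.000349). Pericyte and smooth muscle genes passed it with more promoter peaks, 86.7%, in the pooled list (0.0428) and in either single-replicate list (0.0243 and 0.0441).

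**Figure D2:**
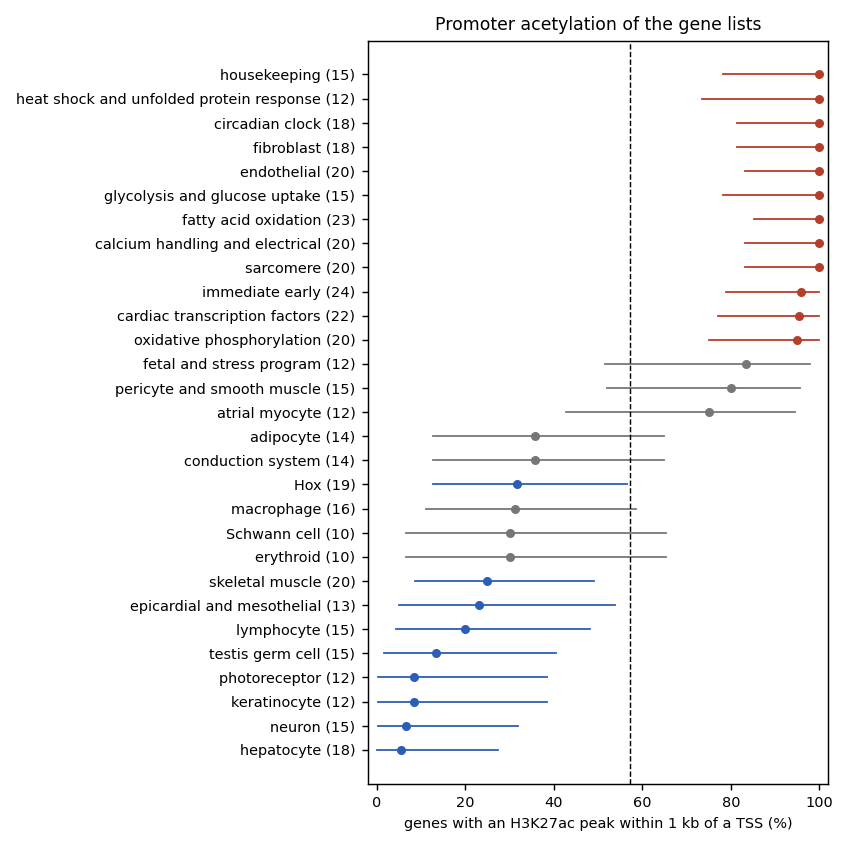
Percent of the genes of each list with an H3K27ac peak within 1 kb of a TSS (x axis), with 95% exact binomial intervals as lines and the number of genes in brackets. Red lists lie above and blue lists below the other protein-coding genes at an adjusted p under 0.05, grey lists do not differ by that test, and the dashed line marks 57.3%, the share of all protein-coding genes.

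Enhancers were included by counting the length covered by peaks from 50 kb before to 50 kb after each gene. Heart regulators stood in the longest acetylated surroundings. The median was 23.8 kb for cardiac transcription factors, 21.7 kb for endothelial genes, 20.3 kb for sarcomere genes and 20.1 kb for calcium handling and electrical genes. Random lists of the same gene lengths averaged 5.22, 5.03, 4.97 and 5.54 kb. The permutation p of these 4 lists and of the immediate early genes (13.7 kb against 3.41 kb) was 0.0002, the smallest that 10000 random lists can give, and 0.00116 after Benjamini-Hochberg adjustment.

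Among cardiac transcription factors, Nfia had 92.4 kb, Gata4 48.1 kb, Tead1 42.5 kb and Myocd, a coactivator of serum response factor, 39.3 kb. Ldb3, a Z-disc protein, led the sarcomere genes with 42.8 kb, followed by Actn2 (36.4 kb), Myom1 (34.4 kb) and Lmod2 (31.9 kb). Cacna1c, the pore of the L-type calcium channel, had 48.9 kb, Atp2a2, the calcium pump of the sarcoplasmic reticulum, 42.2 kb, Jph2 42.1 kb and Kcnq1 40.5 kb. Endothelial genes were led by Eng (58.3 kb), Pecam1 (53.3 kb), Kdr, the main receptor of the growth factor VEGF (47.7 kb), and Notch1 (46.1 kb).

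Metabolic lists were also long. Fatty acid oxidation genes had a median of 13.7 kb (adjusted permutation p = 0.0029), with Cd36, the fatty acid transporter, at 64.5 kb, Ppara at 36.2 kb, Ppargc1a at 32.9 kb and Lpl at 29.8 kb. Glycolysis and glucose uptake genes had 14.9 kb (0.0029), led by Slc2a4, the insulin-responsive glucose transporter, at 26.9 kb and Hk2 at 24.9 kb. Oxidative phosphorylation genes, at 6.78 kb, did not differ from random lists (0.24).

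Pericyte and smooth muscle genes had a median of 16.1 kb (adjusted permutation p = 0.0029), with Abcc9 at 33.9 kb and Mylk at 29.2 kb, and fetal and stress program genes 14.0 kb (0.00422), with Myh7 at 28.0 kb and Tnni1 at 23.9 kb. The window of Myh7 overlaps that of Myh6, its neighbour, and the window of Tnni1 holds the sarcomere gene Tnnt2. These lengths are therefore not particular to Myh7 or Tnni1, and the promoter peak of Tnni1 was 0.606 kb wide. Clock genes had 13.3 kb (0.00422), with Nr1d1, a repressor in the clock, at 49.3 kb and Tef at 37.6 kb. Heat shock genes had 14.3 kb (0.00483), with Hspb1 at 22.6 kb, and housekeeping genes 14.3 kb (0.00422), with Eef2 at 33.0 kb. Fibroblast genes had 10.6 kb (0.0452), with Fbn1 at 28.6 kb and Col1a1 at 23.2 kb. Dusp1 (67.6 kb) and Klf2 (36.6 kb) led the immediate early genes.

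Keratinocyte genes (0.11 kb, adjusted permutation p = 0.0419) and neuron genes (0.879 kb, 0.0427) had less acetylated length than random lists, with none within 50 kb of Flg, Ivl, Krt1 and Krt14, or of Elavl4, Gad1, Gad2 and Neurod1. The remaining lists did not differ from random lists. Their medians were 7.92 kb for adipocyte, 7.12 kb for photoreceptor, 6.82 kb for atrial, 4.49 kb for skeletal muscle, 3.97 kb for conduction system, 3.81 kb for lymphocyte, 3.63 kb for erythroid, 3.57 kb for epicardial and mesothelial, 3.47 kb for testis germ cell, 2.73 kb for Schwann cell, 1.55 kb for macrophage, 1.45 kb for hepatocyte and 0.617 kb for Hox genes, with adjusted p from 0.207 to 0.97. Gnat1, a rod photoreceptor gene without a promoter peak, had 30.6 kb in its window.

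Thus 13 lists lay above random lists and 2 below. Against random lists matched also on having a promoter peak, 8 lay above, among them photoreceptor genes (0.0164), and 0 below. The calls for fibroblast, glycolysis, fetal and stress, clock, heat shock and housekeeping genes ended (adjusted p from 0.0567 to 0.364), as did those for keratinocyte (0.616) and neuron genes (0.999). Among the stronger peaks the calls for keratinocyte (0.094), neuron, pericyte and smooth muscle, housekeeping (0.0616 each) and fibroblast genes (0.184) ended. The fibroblast call also ended in either single-replicate list (0.143 and 0.0609), and windows of neighbouring genes overlap, so genes of a list are not independent.

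**Figure D3:**
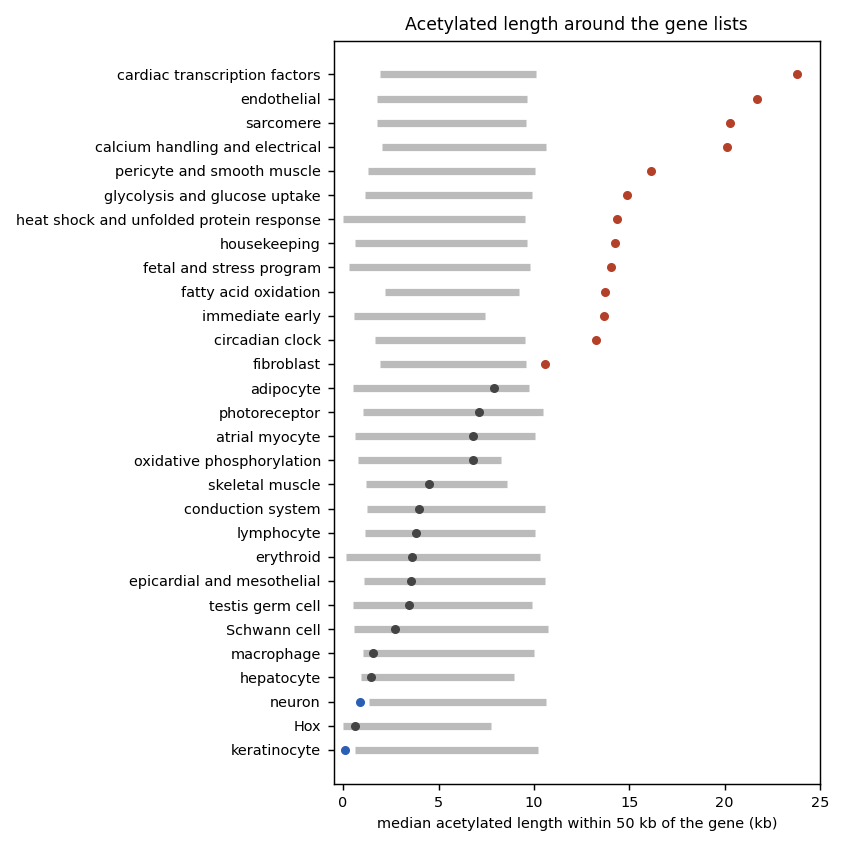
Median length covered by peaks from 50 kb before to 50 kb after the genes of each list (x axis, kb; points), with the central 95% of medians of 10000 random lists of the same gene lengths as grey bars. Red points lie above and blue points below random lists at an adjusted p under 0.05; the cardiac transcription factors are highest at 23.8 kb.

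The widest single peaks lay at genes of different kinds, and no theme among them was tested. The widest, 22.4 kb on chromosome 5 from 17827522 to 17849909, lay inside Cd36 (chromosome 5, 17781690 to 17888801) over internal TSSs. Other wide peaks at protein-coding genes were those of Adgrg1 (17.9 kb), E030018B13Rik (17.5 kb, a peak that lies inside Klf13), Mef2d (15.7 kb), Gata4 (15.5 kb), Elk3 (14.6 kb), Bcl6 with the overlapping Gm37419 (13.6 kb) and Nfic (13.4 kb). Mef2d and Gata4 encode transcription factors of heart muscle. A peak of 21.3 kb covered TSSs of the long non-coding RNA Neat1 on chromosome 19, from 5831133 to 5852385.

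Peaks close to one another were joined into 20739 regions, 8609 of them a single peak. The region with most covered length, 111.4 kb in 69 peaks, lay in Tns1, which encodes the focal adhesion protein tensin (chromosome 1, 73913904 to 74125200). The next lay at Rbpms, an RNA-binding regulator of muscle splicing (104.5 kb), and across Col4a1 and Col4a2, the collagen IV chains of basement membranes (103.9 kb). Further long regions lay at Ablim1 (89.8 kb), Snrk (88.4 kb), Tcf4 (87.9 kb), Nrp1, a coreceptor for VEGF (68.0 kb), Nfia (62.5 kb) and Fam53b (61.3 kb). Another 10 held 54.0 to 60.4 kb and had Cuedc1, Trak1, Nfib, Ppara, Rapgef2, Itpkb, 2010111I01Rik, Vps13d, Susd6 and Frmd8 as nearest genes. Of the fixed gene lists only Nfia and Ppara overlapped the 20 longest regions, each with part of the gene. The ranking depends on the joining distance: with peaks joined within 5 kb, 8 of these 20 remained among the 20 longest.

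The X chromosome was sparsely acetylated in these female hearts, and no peak lay on the Y chromosome. X held 1175 peaks, and its density was 0.273 times that of the autosomes (95% interval 0.258 to 0.289, from the exact binomial interval of the share of peaks on X), whose density was 25.1 peaks per Mb. Per protein-coding gene X had 1.24 peaks, below the lowest autosome, chromosome 7, with 1.84. A promoter peak was present at 37.2% of X genes, against 47.6% on the lowest autosome. Peaks at promoters of protein-coding genes on X had a median deposited fold of 7.40 and a median width of 778 bp, against at least 9.25 and 1025 bp on every autosome, while the other peaks on X had a fold of 3.89, within the autosomal range of 3.83 to 4.08.

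Genes that escape X inactivation had strong promoter peaks. The deposited fold was 31.6 at Ddx3x, 25.8 at Eif2s3x, 20.2 at Kdm6a and 15.8 at Kdm5c, and 9.67 at Xist, the RNA that coats the inactive X. Their partners on the Y chromosome, Ddx3y, Eif2s3y, Uty and Kdm5d, had no peak within 50 kb in any of the 4 lists, which fits the female label. The density on X was 0.295 times the autosomal one among the stronger peaks. Chromosomes were compared as values, without a test.

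**Figure D4:**
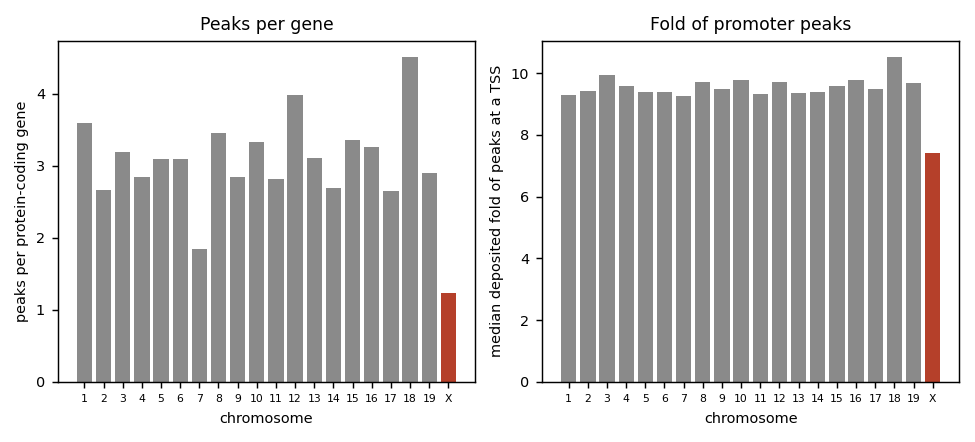
Peaks of the replicated list per protein-coding gene (left y axis) and median deposited fold of peaks at promoters of protein-coding genes (right y axis) for each chromosome (x axis), with X in red. X is lowest in both, at 1.24 peaks per gene and a fold of 7.40.

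The last question of sequence was which transcription factor sites marked the 37273 distal peaks. Sites for MEF2, TEAD, NKX2-5, ETS, E-box and AP-1 factors were more frequent than in windows 5 kb away that touched no peak. They were so by more than shuffles of the same sequence. MEF2, TEAD and NKX2-5 have members in the list of cardiac transcription factors. So do GATA, SRF, MEIS, TBX and ERR, whose sites did not go beyond their shuffles. In whole heart tissue a site does not show the cell type in which it acts. The consensus of MEF2, the myocyte enhancer factors, was found in 10.9% of 500 bp summit windows and in 8.66% of 58679 control windows. Its odds ratio, stratified by GC content, was 1.76 (95% interval 1.68 to 1.84), and the 20 shuffles of this consensus gave 0.83 to 1.23. The ETS consensus, of a family active in endothelium, had an odds ratio of 1.55 (1.30 to 1.84), the E-box CAGCTG of muscle and other cells 1.39 (1.34 to 1.43), AP-1 1.37 (1.31 to 1.43), TEAD 1.25 (1.20 to 1.30) and NKX2-5 1.11 (1.07 to 1.14). Each of these 6 exceeded all its shuffles. For NKX2-5 the margin was small, 1.106 against a highest shuffle of 1.098, with 25.98% of peaks against 25.33% of controls. Over 7 alternative settings TEAD did so in 7, MEF2 and the E-box in 6, AP-1 and NKX2-5 in 5 and ETS in 3, so the call for ETS is weak.

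The consensus sequences of GATA (odds ratio 1.15), MEIS (1.16), ERR (1.16), SRF (1.17) and C/EBP (1.38) were within the range of their shuffles. C/EBP, found in few windows, was above all its shuffles in 3 of 7 alternative settings and reached 3.13 (1.46 to 6.71) among the stronger peaks. TBX (0.836) and the sites for HNF4, a factor of liver (1.02), and REST, a repressor of neuronal genes (0.871), were also within range. CTCF reached 2.03 (1.69 to 2.43), but only 7 of its shuffles were frequent enough to give an odds ratio, as for NRF1 (1.56), and HNF1 was too rare for one. In 1 kb windows, with 11 such shuffles, CTCF had 1.89 and exceeded them all. A consensus match does not show binding. In 200 bp windows only TEAD (1.115, highest shuffle 1.105) and NKX2-5 (1.13, highest shuffle 1.126) exceeded all their shuffles, by small margins. There MEF2 fell to an odds ratio of 1.06 (0.978 to 1.15), with 2.52% of peaks against 3.48% of controls. ETS fell to 1.02 and CTCF to 0.403.

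**Figure D5:**
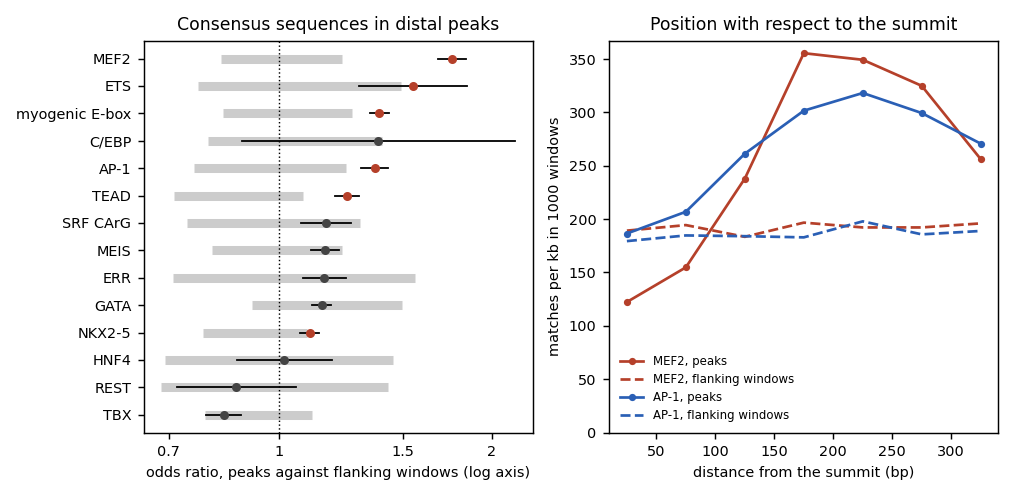
Left, odds ratio of each consensus sequence in distal peaks against flanking windows (x axis, log scale; points with 95% intervals), with the range of shuffles of the same consensus as grey bars and consensus sequences above all shuffles in red. Right, matches per kb in 1000 windows (y axis) by distance from the summit (x axis, bp) for MEF2 and AP-1; MEF2 rises from 122.3 at the summit to 355.5 at 150 to 200 bp.

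Peaks private to 1 replicate list were used to ask whether marker genes of other cell types went with either pool. Most private peaks, 19779 against 2987, were in replicate 2, as were most private promoters, 644 genes against 58, beside 12042 genes with a promoter peak in both lists. Private peaks near sarcomere genes numbered 17 in replicate 1 and 131 in replicate 2, a difference at percentile 0.08 of random lists matched on gene length. Pericyte and smooth muscle genes had 13 and 86 (percentile 0.1), endothelial genes 18 and 95 (0.825), atrial genes 5 and 36 (3.77), erythroid genes 2 and 11 (60.85), adipocyte genes 2 and 35 (3.555) and macrophage genes 10 and 35 (55.35). Of 29 lists, 11 lay outside the central 95% of such random lists. When these were matched also on acetylated length, 4 did, against 1.45 by chance. These were sarcomere genes (percentile 1.63), atrial genes (1.04) and Hox genes (0), with a larger excess in replicate 2 than the random lists, and fatty acid oxidation genes (99.5), with a smaller one, at 9 and 49 private peaks. With 1 list per replicate no p can be given.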

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

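Of 565 values of comparisons recomputed under alternatives, 496 kept their direction and side of the threshold or their size, and none changed direction. Of 29 lists, 21 kept their promoter call and 19 their length call under all alternatives run. The filter at q, the omission of genes sharing a promoter window and the motif controls away from TSSs were chosen after the data had been seen. The cause of the changes that follow was not tested. With 50% reciprocal overlap, 51.3% of replicate 1 peaks and 46.7% of replicate 2 peaks were shared. When an overlap of 50% of the private list's peak was asked for, 31976 peaks were private to replicate 2. Among peaks with a fold at or above the median the shares were 96.4% and 74.8%, private peaks numbered 32 and 1141, 49.6% of peaks lay at a TSS, the X ratio was 0.295, and 9 of the 20 longest regions remained. There the epicardial promoter share was 23.1% (Fisher's exact test, adjusted p = 0.0629) and the macrophage share 6.25% (0.000349). Length ratios to random lists there were 1.70 for fibroblast (0.184), 2.51 for housekeeping (0.0616), 2.33 for pericyte (0.0616), 0.142 for neuron (0.0616) and 0 for keratinocyte genes (0.094), leaving 0 lists below. Windows of 500 bp and 2.5 kb put 29.6% and 40.9% of peaks at a TSS. At 500 bp, shares of 25% for macrophage (0.0275) and 20.0% for erythroid genes (0.0309) passed. At 2.5 kb, 91.7% for fetal and stress (0.0272) and 86.7% for pericyte genes (0.0445) passed, and 40.0% for skeletal muscle (0.125) did not. With the 5' end of the gene only, and without genes sharing a window, the epicardial share of 23.1% missed the threshold (0.0621 and 0.0656), as did 25% for Hox genes without shared windows (0.0589). In the pooled list 25% for macrophage (0.0153) and 86.7% for pericyte genes (0.0428) passed, the ratio was 1.98 for fibroblast (0.0661) and 0.22 for neuron genes (0.0609), and 1 list lay below. With q of 0.05 or less the fibroblast ratio was 2.02 (0.0553). With a 20 kb window 1 list lay below, and the keratinocyte ratio was 0 (0.141). Without peaks near a TSS the ratios were 1.46 for glycolysis (0.878), 5.78 for housekeeping (0.0701), 0 for keratinocyte (0.878) and 0.389 for neuron genes (0.878), 0 lists lay below, and 8 of the 20 longest regions remained, as with joining within 5 kb. Against random lists matched on promoter peaks, 8 lists lay above and 0 below. Ratios were 1.64 for clock (0.0749), 1.92 for fetal and stress (0.0664), 1.35 for fibroblast (0.364), 1.81 for glycolysis (0.0567), 1.61 for heat shock (0.118), 1.69 for housekeeping (0.0664), 0.101 for keratinocyte (0.616) and 0.861 for neuron genes (0.999), while photoreceptor genes passed with 5.89 (0.0164). In motif windows of 200 bp, 2 consensus sequences exceeded their shuffles, and the CTCF odds ratio of 0.403 lay on the other side of 1. Using the list of either biological replicate alone gave ranges: promoter shares of 30.8% for epicardial (0.0646 and 0.108), 83.3% to 91.7% for fetal and stress, 86.7% for pericyte, 25% to 37.5% for macrophage and 20.0% to 30.0% for Schwann cell genes; length ratios of 1.80 to 2.00 for fibroblast, 0 to 0.0722 for keratinocyte and 0.143 to 0.289 for neuron genes; 0 to 2 lists below; 13 to 14 of the 20 longest regions; and 32.38% to 36.15% of peaks at a TSS. Of 191 other values, 92 moved, chiefly counts of private peaks near lists. No paired analysis was possible because there is 1 group. Unknown depth limits what the absence of a peak can show.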

Other observations

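The gene families and isoform pairs in this paragraph and the next, and the position of sites around summits, were chosen after the peak lists had been seen. Large families of sensory genes were without promoter acetylation in the heart. Of 1092 olfactory receptors 6 had a promoter peak, or 0.549% (95% exact interval 0.202% to 1.19%), and of 326 vomeronasal receptors 1. Of 66 genes whose symbols start with Def and end in a digit, 3 had one. Many of these are defensins, which are antimicrobial peptides, but selection by symbol can include other genes. At the other end stood the machinery of mitochondria and protein turnover. Promoter peaks were present at 37 of 37 genes with Nduf symbols, which name mainly complex I subunits, and at 78 of 78 mitochondrial ribosomal proteins. The counts were 78 of 80 for cytosolic ribosomal proteins and 37 of 39 for proteasome subunits. The medians of acetylated length in these families were 6.43 to 7.17 kb, against 4.39 kb over all protein-coding genes. Of 394 zinc finger genes of the Zfp series 81.5% had a promoter peak (77.3% to 85.2%), with a median length of 3.65 kb. Lengths of the families were not matched on gene length.

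In 18 pairs of a heart or oxidative-muscle gene and a relative used elsewhere, the heart member had a promoter peak in all 18 and the relative in 9. All heart members but Ckmt2 belong to lists reported above, and many relatives to the skeletal muscle list. The pairs are thus no separate support for the results of those lists. The length was greater at the heart member in 14 pairs, with medians of 13.8 kb and 8.96 kb. Lengths in the pairs were not matched on gene length, which sets how much a window can hold, and windows of neighbouring genes overlap. Atp2a2 had 42.2 kb and its skeletal counterpart Atp2a1 11.2 kb without a promoter peak, Ryr2 28.1 kb and Ryr1 12.9 kb, and Slc2a4 26.9 kb while the liver transporter Slc2a2 had none. The length was smaller at the heart member in 4 pairs, Casq2 and Casq1, Mybpc3 and Mybpc2, and Tnnt2 (12.6 kb) and Tnnt3 (23.1 kb), and Tnni3 (18.8 kb) and Tnni2 (25.5 kb), and neither Tnnt3 nor Tnni2 had a promoter peak. The region around Malat1 and Neat1 on chromosome 19, 2 abundant nuclear RNAs, held 54.0 kb of acetylation in 10 peaks, with single peaks of 14.8 kb and 21.3 kb.

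Replicate 2 peaks were missing from the list of replicate 1 in 32.2% of cases. Weak peaks were the missing ones, with 0.0391% missing in the highest of 4 classes of fold. The same held in the other direction, with 0% missing, so a weaker enrichment in replicate 1 cannot be told apart from other causes of loss near the threshold. Different shares of cell types in the pools predict that more than 5 lists stand apart, and at most 3 if they do not. The count was 4, between these bounds, so a small difference in cell types cannot be told apart from chance here. Depth, which is unknown, and a biological difference between the pools may both remain, and neither was tested.

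X had fewer peaks per Mb than the autosomes. A lower gene density is argued against by 1.239 peaks per protein-coding gene, below every autosome. Lower acetylation per promoter on X predicts a lower fold there, and the median of 7.403 lay below every autosome, while the other peaks on X, at 3.887, lay within the autosomal range, although they too were few. A hypothesis is that reads from the silent X dilute the fold at promoters active on 1 copy, which may also push weak peaks below detection. Silent gene families on X, such as those of the testis, may contribute as well. No male or single-allele value is used here, so X inactivation itself was not tested.

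MEF2 sites were fewer at the summits of distal peaks than beside them. Their density within 75 bp of the summit was 0.409 times that at 150 to 350 bp (95% bootstrap interval 0.379 to 0.443), while control windows gave 0.992. The ratio was 0.159 for CTCF (0.0919 to 0.23; 23 central matches, controls at 0.691 and no usable shuffle), 0.567 for ETS and 0.649 for AP-1 (0.608 to 0.689). Base composition around the summit stays open for MEF2. Its 20 shuffles all had fewer matches at the summit, with ratios of 0.346 to 0.811 and a median of 0.716, and 2 were as low. For AP-1 the lowest shuffle had 0.875. Other sites had a smaller dip or none. The ratio was 0.823 for SRF, 0.834 for GATA, 0.867 for ERR and 0.87 for TEAD. It was 0.971 for the E-box (0.94 to 1.01), 1.01 for NKX2-5 (0.969 to 1.05), 1.02 for MEIS and 1.11 for TBX (1.02 to 1.21). A hypothesis is that summits lie on acetylated nucleosomes beside the sites of some factors. It does not cover the sites without a dip, and it has no direct test in peak lists.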
